A study of Mus musculus with 24 samples.

How the data were processed

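Fat tissue of 4 depots from mice on 2 diets was measured on 24 Affymetrix whole transcript arrays, 3 per group of depot and diet, each with 250 ng of total RNA pooled from 2 mice. Per the labels' protocols, RNA was extracted with a Qiagen minilipid kit, converted to cDNA with the Ambion WT Expression Kit and labelled with the Affymetrix WT Terminal Labeling kit. The deposited table holds log2 values, which the authors made with RMA in the R package affy per the submitters' processing notes, with no version given. The genome build is not given in the sources used here, and no coordinates were used. Raw intensity files were not analysed here. The array medians and ranges were checked and fit a log2 scale, and no further normalization was applied.

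The table had 34760 probe sets. Of these, 21640 named 1 gene symbol, 1321 named several and 11799 had no symbol in the annotation used here, and the last 2 kinds were left out. For the 954 genes with several probe sets, the probe set with the highest mean over all 24 arrays was kept, which left 19937 genes. A gene was tested when its value was above 6.85, the 30th percentile of all values, in at least 3 arrays, and 16618 genes passed this filter.

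All 24 arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) as 8 groups of diet and depot, with no other term. The fit had 16 residual degrees of freedom and 4.76 prior degrees of freedom. For each of 16 comparisons, p-values were adjusted by Benjamini-Hochberg over the 16618 genes, and an adjusted p under 0.05 counts as past the test. The comparisons were the 6 pairs of depots under ND, PVAT against each other depot under HFD, HFD against ND in each depot, and 3 interactions that set the diet response of PVAT against that of each other depot. The SE is the moderated standard error of the log2 difference, with a median over genes of 0.129 in the comparisons of depots and of diets and 0.182 in the interactions.

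There were 25 gene lists: brown adipocyte and thermogenesis, white adipocyte enriched, pan-adipocyte, oxidative phosphorylation, fatty acid oxidation, tricarboxylic acid cycle, fatty acid and triglyceride synthesis, cholesterol synthesis, macrophage, cytokines and chemokines, T lymphocyte, thymocyte, B lymphocyte and lymph node, extracellular matrix, endothelium, smooth muscle, skeletal muscle, cardiac muscle, mesothelium, epididymis epithelium, nerve and Schwann cell, positional homeobox and T-box, vasoactive, circadian clock, and immediate early. Some genes stand in several lists, such as Agt in the white adipocyte and vasoactive lists. Each list was tested with camera at a preset correlation between genes of 0.01, with p-values adjusted over the 25 lists of a comparison, and again with camera at the correlation estimated from the data and with fry. Camera compares a list with the other genes, while fry tests whether the members move on balance in one direction. Members past the test were counted over all genes and adjusted over the list alone. Across the 16 comparisons 189 list calls passed with the preset correlation, and 8 of them also passed with an estimated correlation, against 45, these 8 included, without HFD PVAT 2 and HFD VAT 2. The 8 were skeletal muscle and mesothelium in PVAT against BAT under ND and under HFD, mesothelium in BAT against VAT, and mesothelium, T lymphocyte and B lymphocyte in SAT against VAT. By fry, 112 of the 189 passed.

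The genes named were set by a rule. For each of 7 main comparisons (PVAT against the 3 other depots under ND, and the diet effect in 4 depots) the rule took the 8 largest differences in each direction among genes past the test whose replicates did not overlap, without gene models known only by a number, olfactory receptors, small RNAs and pseudogenes. It added up to 4 members past the test of each list that passed, 15 fixed genes (Ucp1, Cidea, Ppargc1a, Prdm16, Dio2, Elovl3, Lep, Adipoq, Retn, Adgre1, Cd68, Itgax, Ccl2, Tnf and Saa3) and, where few genes passed, those with the smallest p up to 5 per direction. Other comparisons took the 3 largest per direction and interactions the 5 largest. The groups, comparisons, tests, lists, filter and this rule were set before the data were examined.

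The brown-white score used genes that differed between BAT and VAT among the 6 HFD arrays of those depots fitted alone, with an adjusted p under 0.05 and a log2 difference of at least 1. Scores of PVAT and another depot under ND were compared by an exact two-sided permutation test. Muscle and immune genes of its axis were list members and genes whose deviations from group means correlated above 0.7 with the mean of a list, over the BAT arrays for muscle and the arrays outside HFD PVAT and HFD VAT for immune lists.

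As the mice are male, the female transcript Xist was low in every array (5.66 to 6.35) and the Y-linked Eif2s3y high (9.08 to 10.1). The labels do not say whether a replicate number stands for the same mice in each depot. Deviations from group means of arrays with the same number were correlated above 0.1 in all 3 pairs for BAT against SAT under ND (0.156, 0.150 and 0.171), SAT against VAT under ND (0.242, 0.309 and 0.176) and HFD against ND in VAT (0.294, 0.281 and 0.256), the last of which cannot come from shared mice. With replicate number as a block these comparisons called 7072, 2606 and 3795 genes, against 6757, 2311 and 3241 without a block, and the unblocked values are reported.

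Simulated values were drawn around each gene's mean with variances from the fitted prior, and 200 genes got known changes in 1 group. For PVAT against BAT under ND, 38.8%, 92.5% and 100% of changes of 0.5, 1 and 2 log2 were recovered (5.52% false calls). For HFD against ND in PVAT the shares were 49.3%, 91.0% and 100% (4.76%). For the interaction of PVAT and VAT they were 13.4%, 79.1% and 100% (5.19%). No simulated array stood apart from its group, so real shares may differ.

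The alternatives were no filter, a filter at the 50th percentile (7.73), the mean of a gene's probe sets, arrays centred on their medians, quantile normalization, eBayes with trend and robust, array weights, replicate number as a fixed block (within diet for depots and interactions, across diets for diet) and diet with replicate number as a random block, only the arrays of the groups compared, a log2 difference of at least 1, and leaving out each array in turn. For the score they were an axis from ND arrays and axis genes with a difference of at least 2, and for the correlations Spearman in place of Pearson. Alternatives chosen after seeing the data were leaving out HFD PVAT 2 and HFD VAT 2, leaving out HFD SAT 2, the score axes without HFD VAT 2 and without muscle or immune genes, and a score of the brown list minus the white list. Array weights were computed gene by gene, a form also chosen after seeing the data, because the default form did not converge.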

Results

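Gene expression was measured on 24 Affymetrix arrays from 4 fat depots of male C57BL/6 mice fed a normal diet (ND) or a high fat diet (HFD, 45 kcal% fat) for 13 weeks from 8 weeks of age. The depots were the fat around the aorta, taken at the lesser curvature of its arch (PVAT), the interscapular brown fat (BAT), the inguinal subcutaneous fat (SAT) and the epididymal visceral fat (VAT). Each of the 8 groups of diet and depot had 3 arrays, and each array carried RNA pooled from 2 mice, so n is 3 pools in every group. Array medians lay between 7.66 and 7.80 on the log2 scale, and the SD of the values within an array ran from 1.64 (HFD SAT 2) to 1.87 (ND VAT 1). The number of arrays limits the precision of every value. After the filter on dim signals, 16618 genes were tested. Differences are given as log2, positive where the first group named was higher, with the standard error (SE) of the fit shown for the leading genes, and adjusted p is from limma. The gene lists were tested with camera, first with a preset correlation between genes and then with the correlation estimated from the data, whose p is given as "with an estimated correlation".

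The arrays placed PVAT closest to BAT. Under ND the Pearson correlation across the tested genes between PVAT and BAT arrays was on average 0.966, against 0.928 for PVAT and VAT and 0.911 for PVAT and SAT, with 0.981 between replicate PVAT arrays (genes are not independent replicates, and no test was made of these values). The first principal component held 48.8% of the variance of the 24 arrays, and the second 14.7%. A brown-white score, the mean of 560 genes higher in HFD BAT minus the mean of 523 genes higher in HFD VAT, was computed for each ND array, so that no array entered both steps. The score was 2.08 ± 0.06 (SD, n = 3) in BAT, 1.30 ± 0.23 in PVAT, -0.55 ± 0.08 in VAT and -0.72 ± 0.21 in SAT. PVAT differed from BAT by -0.78 and lay 1.85 above VAT and 2.02 above SAT, each beyond the spread between replicates. In each case all 3 PVAT arrays fell on one side of the 3 others, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The axis takes in genes of other cell types. Genes of the muscle lists, or correlated with them, made up 189 of the 560, and genes of the immune lists, or correlated with them, 314 of the 523. With axis genes that differ by at least 2, of which 66 of 96 and 49 of 64 were such genes, PVAT lay -1.76 from BAT, 2.18 from VAT and 2.12 from SAT. Further axes were chosen after the data were seen. Without the muscle and immune genes the difference from BAT was -0.51 (2.39 from VAT, 1.99 from SAT), or -0.87 (4.11 and 3.05) on the axis of at least 2. The mean of the brown list minus that of the white list gave -0.32 (3.98 from VAT, 3.16 from SAT). In each case the exact p was again 0.1.

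**Figure D1:**
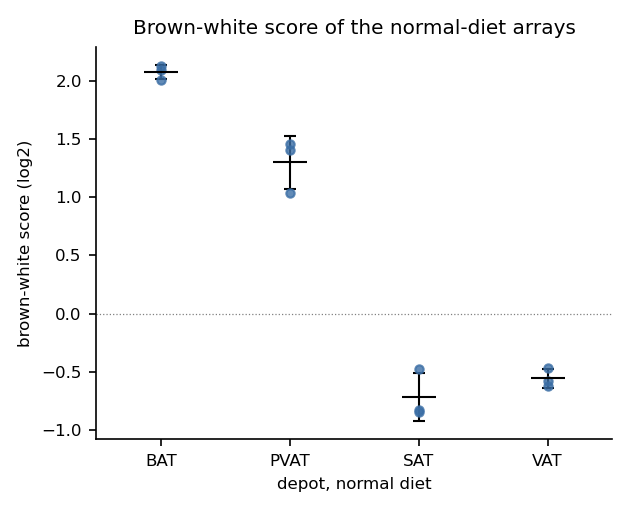
Brown-white score (log2, vertical axis) of the 12 ND arrays by depot, one point per array, with the group mean and SD. The PVAT arrays, with a mean of 1.30, lie between BAT at 2.08 and both white depots at -0.55 and -0.72.

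The first comparison asked how far PVAT differs from BAT under ND. Brown fat genes were high in both depots. Ucp1, the uncoupling protein of thermogenesis (probe set 10573152), had a mean of 13.62 ± 0.08 in PVAT and 13.66 ± 0.20 in BAT (SD, n = 3, log2 difference -0.05, SE 0.80, limma adjusted p = 0.989). PVAT carried more of the genes of mesothelium, the cell layer that lines body cavities. Gpm6a, a membrane glycoprotein, was 5.33-fold higher in PVAT (9.81 ± 0.20 against 7.39 ± 0.20, log2 difference 2.41, SE 0.18, adjusted p = 1.43e-07). BAT carried more of the genes of skeletal muscle, and Neb, the giant protein of the thin filament, was 9.64-fold lower in PVAT (-3.27, SE 0.26, adjusted p = 1.76e-07). In all, 374 genes passed the test, 193 higher and 181 lower in PVAT, of which 72 and 78 differed at least by a log2 of 1. By the naming rule, genes named as largest had no overlap of replicates. Of all tested genes, 23.4% had no overlap, where chance gives 10%.

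Of the 16 skeletal muscle genes, 15 were lower in PVAT and 0 higher (median -2.46, adjusted p = 2.92e-54, and 0.00236 with an estimated correlation). Adjusted over the list alone, 16 were lower. The largest were Pvalb (-3.19), Tnnt3 (-3.01), Myh1 (-2.99), Atp2a1 (-2.97), Casq1 (-2.82) and Myh4 (-2.80), which encode calcium handling and contractile proteins of fast fibres, with Myot, a sarcomere protein outside the list (-2.90). These genes are markers of another tissue: their mean was 10.97, 10.94 and 9.88 in the ND BAT arrays and between 8.17 and 8.23 in the ND PVAT arrays. Of the 13 mesothelium genes, 9 were higher and 0 lower (11 higher when adjusted over the list alone, median 0.68, adjusted p = 9.71e-24, and 0.00144 with an estimated correlation). The uroplakins Upk3b (2.35) and Upk1b (2.20) and the membrane protein Lrrn4 (1.27) led them, and Pkhd1l1, outside the list, was higher by 2.39. In this comparison skeletal muscle and mesothelium alone passed with an estimated correlation.

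Of the 17 genes of B lymphocytes and lymph node, 5 were higher in PVAT and 0 lower (14 higher when adjusted over the list alone, median 0.98, adjusted p = 6.21e-13, but adjusted p = 0.23 with an estimated correlation). They included Jchain, the joining chain of secreted antibodies (2.41), Cd79a of the B cell receptor (2.30), Ms4a1 (2.20) and the IgE receptor Fcer2a (1.81), with the antibody segment Igkv4-91 (3.02, SE 0.73). The list mean was 8.22, 9.67 and 8.35 in the ND PVAT arrays and 7.46 to 7.62 in ND BAT. Igkv4-91 and Fcer2a lost the call without any 1 array other than ND PVAT 1 (adjusted p from 0.0663 to 0.342), and without ND PVAT 2 so did Ms4a1 (1.45, adjusted p = 0.143), Cd79a (1.68, 0.108) and Jchain (1.91, 0.0811). Jchain also lost it without ND PVAT 3 (0.0542), Cd79a without ND BAT 1 or ND BAT 2 (0.0572 and 0.0654), and Ms4a1 without any 1 of the BAT arrays (0.0531 to 0.0794).

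The T lymphocyte list (0 of 16 members past the test, median 0.24, adjusted p = 0.00375) and the macrophage list (0 of 27, median 0.39, adjusted p = 0.00953) were higher in PVAT with the preset correlation only (adjusted p = 0.768 and 0.836 with an estimated correlation). The same held for cytokines and chemokines, with 2 of 23 members higher (median 0.33, adjusted p = 0.0187, but adjusted p = 0.617 with an estimated correlation), where the alarm cytokine Il33 was 3.09-fold higher (1.63, adjusted p = 4.35e-05). Without ND PVAT 2 these lists lost the call (T lymphocyte 0.09, adjusted p = 0.377, macrophage 0.20, 0.156, cytokines 0.13, 0.0665), as did macrophage and cytokines without ND BAT 3 (adjusted p = 0.14 and 0.0533). Of 33 positional homeobox and T-box genes, 4 were lower in PVAT and 0 higher (7 lower when adjusted over the list alone, median -0.05, adjusted p = 0.00341, but adjusted p = 0.617 with an estimated correlation). These were the transcription factors Tbx15 (-1.97), Zic1 (-1.01), Hoxc6 (-0.97, adjusted p = 0.0577 without ND PVAT 3) and Hoxc5 (-0.90). Of 17 immediate early genes 1 was higher (3 over the list alone, median 0.37, adjusted p = 0.00035, but adjusted p = 0.559 with an estimated correlation), the messenger RNA decay factor Zfp36 (0.80), which lost the call without any 1 array other than ND PVAT 1.

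Lists of the fat cell itself did not pass in the fit of all arrays. The brown adipocyte list had 1 of 23 members lower (median -0.11, adjusted p = 0.122), namely Zic1, and the white adipocyte list 1 of 19 higher (median 0.15, adjusted p = 0.0844). No member of the lists of oxidative phosphorylation (54 genes, median -0.02), fatty acid oxidation (19, -0.03), tricarboxylic acid cycle (16, -0.06), fatty acid synthesis (21, -0.06) or pan-adipocyte genes (17, 0.07) passed by limma at an adjusted p under 0.05. The thermogenic genes Cidea (-0.13), Ppargc1a (-0.16), Prdm16 (-0.08), Dio2 (0.18) and Elovl3 (-0.27) and the adipokines Lep (0.51), Adipoq (0.19) and Retn (0.73) did not pass either (adjusted p from 0.107 for Retn to 0.952 for Cidea). HFD PVAT 2 and HFD VAT 2, arrays that stood apart from their groups, enter the ND comparisons through the shared estimate of the spread alone. A fit without them, chosen after the data were seen, gave the same differences. In it the brown (lower, adjusted p = 0.0366) and white lists (higher, 0.0366) passed with the preset correlation, though not with an estimated one (adjusted p = 0.579 and 0.554 with an estimated correlation). So did the cardiac muscle (0.0107), nerve (0.0366) and vasoactive lists (0.0378, adjusted p = 0.579, 0.48 and 0.48 with an estimated correlation), all higher in PVAT. Retn passed as well (adjusted p = 0.0236). The count of 374 was 191 without ND PVAT 3, 207 without ND BAT 2, 228 without ND BAT 1 and 230 without ND PVAT 2, and 1125 with array weights.

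The second comparison asked how PVAT differs from SAT, a subcutaneous white depot. Most thermogenic and mitochondrial genes were higher in PVAT and lymphocyte genes lower, but as sets they did not pass with an estimated correlation in the fit of all arrays (lowest adjusted p of any list 0.0775). Ucp1 was 24.4-fold higher in PVAT (13.62 ± 0.08 against 9.0 ± 0.44, log2 difference 4.61, SE 0.80, adjusted p = 0.000171). Elovl3, a fatty acid elongase of brown fat (4.23), Slc27a2, a fatty acid transporter (4.15), the cytochrome oxidase subunit Cox7a1 (4.13), Pank1 of coenzyme A synthesis (3.78), Cidea (3.73), Acot11 (3.70) and Kng2 (3.66) followed. Lowest in PVAT were the positional gene Hoxc8 (-3.33), Apol7c (-3.16), Dapl1 (-2.71), Ms4a4c (-2.69) and Ms4a4b (-2.67). The test called 4893 genes, 2394 higher and 2499 lower in PVAT (581 and 584 by a log2 of at least 1). Among all tested genes, 47.6% had no overlap between the groups, where chance gives 10%. Without HFD PVAT 2 and HFD VAT 2 (chosen after the data were seen) 6 lists passed with an estimated correlation: brown adipocyte (adjusted p = 0.00368), tricarboxylic acid cycle (0.00753), oxidative phosphorylation (0.00964), fatty acid oxidation (0.00964), mesothelium (0.0118) and fatty acid synthesis (0.0456), while T (0.0857) and B lymphocyte lists (0.154) did not.

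Of 23 brown adipocyte genes 20 were higher and 0 lower (median 2.14, adjusted p = 7.5e-15, but adjusted p = 0.112 with an estimated correlation). They included Dio2, which activates thyroid hormone (3.12, 8.71-fold), the coactivator Ppargc1a (2.14) and the regulator Prdm16 (0.88). Oxidative phosphorylation had 52 of 54 members higher (median 1.36, adjusted p = 2.68e-33, but adjusted p = 0.112 with an estimated correlation), such as Ndufa1 (2.16), Cox5a (2.10) and Sdhd (2.10). Fatty acid oxidation had 18 of 19 (median 1.68, adjusted p = 1.9e-16, but adjusted p = 0.12 with an estimated correlation), led by the carnitine carrier Slc25a20 (2.48) and Acadvl (2.48). In the tricarboxylic acid cycle 16 of 16 were higher (median 1.75, adjusted p = 7.5e-15, but adjusted p = 0.13 with an estimated correlation), with Sucla2 (2.36) and Suclg1 (2.33). Fatty acid and triglyceride synthesis had 19 of 21 higher (median 1.0, adjusted p = 7.62e-12, but adjusted p = 0.112 with an estimated correlation), with Elovl6 (2.74), Acacb (1.94) and Acly (1.88). Cholesterol synthesis had 10 of 16 higher (median 0.78, adjusted p = 7.38e-07, but adjusted p = 0.134 with an estimated correlation), with Idi1 (1.62) and Insig1 (1.07).

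Lymphocyte genes were lower in PVAT throughout: 16 of 16 T lymphocyte genes (median -1.46, adjusted p = 2.99e-13, but adjusted p = 0.112 with an estimated correlation) and 17 of 17 of B lymphocytes and lymph node (median -1.65, adjusted p = 2.93e-10, but adjusted p = 0.147 with an estimated correlation). Cd3g of the T cell receptor complex (-2.59), the cytokine receptor Il7r (-2.55) and the homing receptor Ccr7 (-2.33) were among the former, and Fcer2a (-2.65), Ms4a1 (-2.47) and the complement receptor Cr2 (-2.39) among the latter. Macrophage genes were lower for 16 of 27 (19 over the list alone, median -1.03, adjusted p = 9.77e-07, but adjusted p = 0.385 with an estimated correlation), among them Mpeg1, a pore-forming protein (-1.77), and Laptm5 (-1.64), while Adgre1 (-1.12, adjusted p = 0.0625), Cd68 (-1.19, 0.0523) and Itgax (-1.03, 0.0836) did not pass. Those 3 passed without HFD PVAT 2 and HFD VAT 2, with the same differences (adjusted p = 0.00967, 0.0133 and 0.000402). Cytokines and chemokines had 10 of 23 lower (median -0.38, adjusted p = 0.00169, but adjusted p = 0.205 with an estimated correlation), with Ccl5 (-2.69) and Ccl8 (-1.97). The extracellular matrix list had 18 of 25 lower (median -0.77, adjusted p = 1.57e-10, but adjusted p = 0.179 with an estimated correlation), with the collagen genes Col6a3 (-1.67) and Col15a1 (-1.57).

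White adipocyte genes split, 12 of 19 lower and 2 higher (median -0.95, adjusted p = 0.000124, but adjusted p = 0.179 with an estimated correlation), with Nnat (-2.63), Hoxc10 (-1.5) and the adipokine Retn (-0.90) lower. Mesothelium genes were higher for 11 of 13 (median 0.82, adjusted p = 1.26e-10, but adjusted p = 0.0775 with an estimated correlation), with Upk3b (2.40) and Upk1b (2.29). Cardiac muscle genes were higher for 8 of 13 (median 1.19, adjusted p = 0.000137, but adjusted p = 0.304 with an estimated correlation). Of these, Actc1 (2.80) and Myl7 (2.40) encode contractile proteins of the heart. The circadian clock list had 5 of 18 higher (median 0.37, adjusted p = 0.00329, but adjusted p = 0.341 with an estimated correlation), with Bhlhe40 (1.60) and Usp2 (1.5). The adipokines Lep (-1.46, adjusted p = 0.028) and Adipoq (-0.39, 0.0185) and the cytokine Tnf (-0.38, 0.0427) were lower, but each of these calls rested on single arrays. Lep did not pass without any 1 of ND PVAT 2, ND PVAT 3, ND SAT 1 and ND SAT 3 (adjusted p up to 0.146), Adipoq without any 1 of ND PVAT 1, ND PVAT 2 and ND SAT 1 (up to 0.0897) and Tnf without any 1 of ND PVAT 1, ND PVAT 3, ND SAT 1 and ND SAT 3 (up to 0.207).

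The third comparison set PVAT against epididymal fat. Most brown genes were again higher in PVAT and most white fat and vasoactive genes lower, but no list of this comparison passed with an estimated correlation in the fit of all arrays (lowest adjusted p 0.0597). Ucp1 was 31.1-fold higher (13.62 ± 0.08 against 8.66 ± 0.78, log2 difference 4.96, SE 0.80, adjusted p = 9.72e-05). Agt, which encodes angiotensinogen (probe set 10582658), was 13.1-fold lower in PVAT (8.30 ± 0.22 against 12.01 ± 0.10, -3.71, SE 0.26, adjusted p = 2.65e-08). The test called 3968 genes, 1740 higher and 2228 lower (452 and 360 by a log2 of at least 1), and 39.7% of the tested genes had no overlap, where chance gives 10%. Cidea, a lipid droplet protein (4.84), Elovl3 (4.77), Cox7a1 (4.47), Cox8b (4.2), Pank1 (4.02), Slc27a2 (3.93) and Acot11 (3.81) were the other largest rises. Hoxc8 (-4.11), Mest (-3.79), Pcbd1 (-3.12), Sult1e1, an estrogen sulfotransferase (-3.09), Nnat (-2.80), Plagl1 (-2.60) and Sncg (-2.51) were, beside Agt, the largest falls. The lists that passed with an estimated correlation without HFD PVAT 2 and HFD VAT 2 were brown adipocyte (adjusted p = 0.00117), tricarboxylic acid cycle (0.00537), oxidative phosphorylation (0.00758), fatty acid oxidation (0.00845), white adipocyte (0.00884), vasoactive (0.0102) and mesothelium (0.0174).

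Brown adipocyte genes were higher for 20 of 23 (median 2.38, adjusted p = 1.59e-19, but adjusted p = 0.0597 with an estimated correlation), Ppargc1a (2.38), Prdm16 (1.21) and Dio2 (3.19) among them. Oxidative phosphorylation had 52 of 54 members higher (median 1.28, adjusted p = 2.68e-36, but adjusted p = 0.0867 with an estimated correlation), such as Cox5a (2.10) and Sdhb (1.89). Fatty acid oxidation had 18 of 19 (median 1.32, adjusted p = 6.52e-17, but adjusted p = 0.0948 with an estimated correlation), with Acadvl (2.42), and the tricarboxylic acid cycle 16 of 16 (median 1.66, adjusted p = 4.09e-16, but adjusted p = 0.0948 with an estimated correlation), with Sucla2 (2.21). Lipid synthesis was higher too: 15 of 21 genes of fatty acid and triglyceride synthesis (median 0.69, adjusted p = 6.06e-09, but adjusted p = 0.0935 with an estimated correlation) such as Elovl6 (2.95), and 8 of 16 of cholesterol synthesis (median 0.47, adjusted p = 0.00015, but adjusted p = 0.245 with an estimated correlation) such as Idi1 (1.31).

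White adipocyte genes were lower for 15 of 19 (median -1.28, adjusted p = 2.04e-10, but adjusted p = 0.0597 with an estimated correlation), with the adipokines Lep (-2.27) and Retn (-1.16), and Adipoq, of the pan-adipocyte list, was lower by less (-0.74). Vasoactive genes were lower for 10 of 15 (median -0.70, adjusted p = 8.68e-06, but adjusted p = 0.0597 with an estimated correlation), with the natriuretic peptide clearance receptor Npr3 (-1.97), the angiotensin converting enzyme Ace (-0.94) and the prostacyclin synthase Ptgis (-0.92) beside Agt. Extracellular matrix genes were lower for 19 of 25 (median -0.77, adjusted p = 1.27e-10, but adjusted p = 0.183 with an estimated correlation), with Col15a1 (-2.05) and Thbs1 (-1.81). Mesothelium genes were lower for 12 of 13 (median -0.81, adjusted p = 7.12e-09, but adjusted p = 0.0597 with an estimated correlation), with Upk1b (-1.43) and Lrrn4 (-1.01), so that PVAT stood between BAT and VAT for these genes. Macrophage genes were lower for 8 of 27 (12 over the list alone, median -0.79, adjusted p = 2.27e-05, but adjusted p = 0.488 with an estimated correlation), with the scavenger receptor Cd163 (-1.16) and the lectin Clec10a (-1.38). The acute phase gene Saa3 was lower (-1.95, adjusted p = 0.0021), and Adgre1, the F4/80 antigen, was lower as well (-1.26, adjusted p = 0.0436), a call lost without any 1 of the 6 arrays (adjusted p from 0.0539 to 0.144).

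Genes of nerve and Schwann cells were higher in PVAT for 6 of 10 and lower for 1 (median 0.40, adjusted p = 0.0023, but adjusted p = 0.183 with an estimated correlation), with the Schwann cell cadherin Cdh19 (2.55) and S100b (1.61). Cardiac muscle genes were higher for 8 of 13 (median 1.21, adjusted p = 2.27e-05, but adjusted p = 0.246 with an estimated correlation), with Actc1 (2.77) and Myl7 (2.28), and skeletal muscle genes for 4 of 16 (median 0.34, adjusted p = 0.00391, but adjusted p = 0.555 with an estimated correlation). Smooth muscle genes were lower for 5 of 15 and higher for 1 (median -0.58, adjusted p = 0.00889, but adjusted p = 0.466 with an estimated correlation), with Synpo2 (-1.34) and the actin Acta2 (-0.99). B lymphocyte genes were higher for 5 of 17 and lower for 1 (median 0.84, adjusted p = 0.00061, but adjusted p = 0.466 with an estimated correlation), and the T lymphocyte list had 0 of 16 past the test (median 0.34, adjusted p = 0.0159, but adjusted p = 0.555 with an estimated correlation). Without ND PVAT 2 the B lymphocyte (0.36, adjusted p = 0.0748), T lymphocyte (0.12, 0.358) and smooth muscle calls (-0.38, 0.079) were lost, the last also without ND VAT 2 (-0.20, 0.126). The epididymis list, whose tissue lies next to VAT, had 0 of 4 measured members past the test (median 0.11, adjusted p = 0.515).

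The white depots were also set against BAT and each other. BAT and SAT differed in 6757 genes (3106 higher in BAT, 3651 lower), BAT and VAT in 5602 (2294 and 3308), and SAT and VAT in 2311 (1028 higher in SAT, 1283 lower). Against SAT, 22 of 23 brown genes (median 2.30, adjusted p = 0.16 with an estimated correlation) and 16 of 16 skeletal muscle genes (median 2.46, 0.16) were higher in BAT. In the same comparison 17 of 17 B lymphocyte genes were lower (median -2.93, adjusted p = 0.16 with an estimated correlation), with Igkv10-96 (-5.28), Ms4a1 (-4.67) and Fcer2a (-4.46) lowest and Slc27a2 (4.6) highest. Against VAT, BAT was higher in 21 of 23 brown genes (median 2.44, adjusted p = 0.0766 with an estimated correlation) and lower in all 13 mesothelium genes (median -1.41, adjusted p = 0.016 with an estimated correlation), with Sult1e1 (-4.73), Agt (-3.96) and Mest (-3.68) the largest falls. A fit without HFD PVAT 2 and HFD VAT 2 brought the brown list past the test with an estimated correlation against SAT (adjusted p = 0.00793) and VAT (0.00269). It did the same for the oxidative phosphorylation (0.0249 and 0.0112), fatty acid oxidation (0.0249 and 0.0127) and tricarboxylic acid cycle lists (0.0225 and 0.0111), and for the white list against VAT (0.0112). SAT exceeded VAT in 16 of 16 T lymphocyte genes (median 1.79, adjusted p = 0.02 with an estimated correlation) and 16 of 17 B lymphocyte genes (median 2.30, 0.0305), with Fcer2a (4.13), Ms4a1 (3.90) and Dapl1 (3.69) highest. It was lower in all 13 mesothelium genes (median -1.57, adjusted p = 0.000486 with an estimated correlation), with Upk1b (-3.71), Pkhd1l1 (-3.47) and Upk3b (-3.31) lowest. No member of the 54 oxidative phosphorylation genes differed between the white depots by limma in the fit of all arrays (median -0.11), where 4266 of all genes had an unadjusted p under 0.05. The SAT and VAT count fell to 1131 without ND SAT 3 and 1510 without ND SAT 2, and rose to 4576 with array weights.

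**Figure D2:**
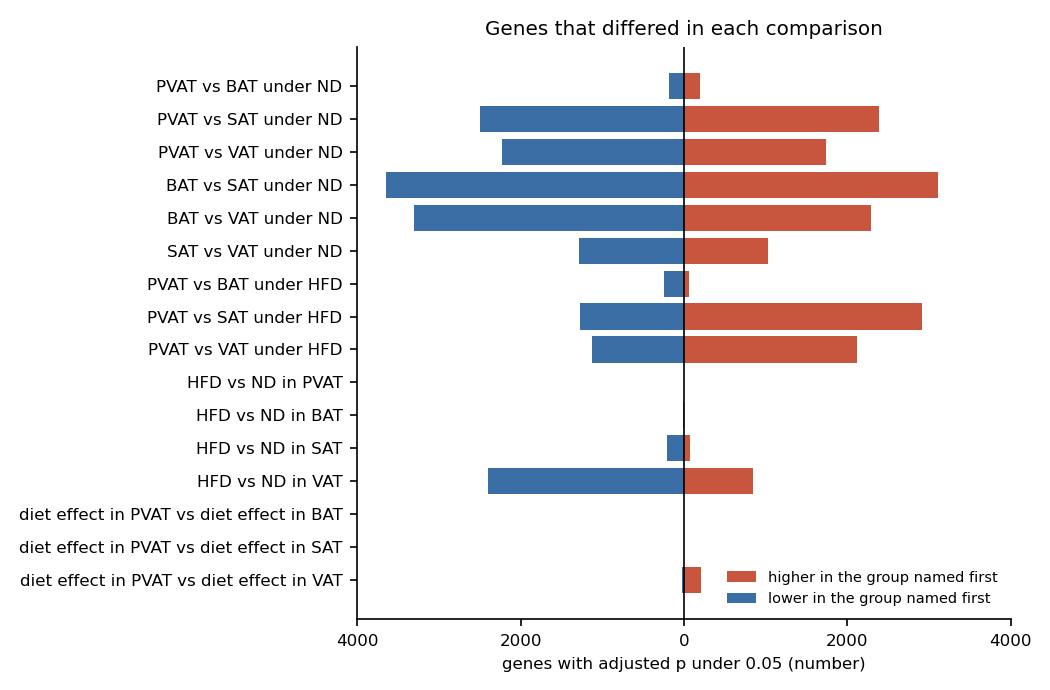
Number of genes higher (right bars) and lower (left bars) in each of the 16 comparisons, at a limma adjusted p under 0.05. PVAT differed from BAT in 374 genes under ND, from VAT in 3968 and from SAT in 4893.

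The comparisons of PVAT with the other depots were repeated under HFD to ask whether its place changed with diet. Against BAT, 311 genes differed (62 higher, 249 lower in PVAT), with 1 of 23 brown genes and 1 of 54 oxidative phosphorylation genes lower. Skeletal muscle genes were lower for 16 of 16 (median -3.50, adjusted p = 1.48e-94, and 0.000223 with an estimated correlation), led by Neb (-4.46), Pvalb (-4.42) and Myot (-4.37). Mesothelium genes were higher for 6 of 13 (median 0.51, adjusted p = 1.37e-18, and 0.0026 with an estimated correlation), with Upk3b (1.78), Gpm6a (1.74) and the opioid precursor Penk (1.74) highest. Against SAT, 4197 genes differed (2920 higher, 1277 lower), with 19 of 23 brown genes higher (median 2.04, adjusted p = 6.04e-13, but adjusted p = 0.119 with an estimated correlation), led by Ucp1 (5.98), Cox7a1 (4.73) and Cidea (4.34), while Ms4a1 (-2.83), Lipf (-2.62) and Fcer2a (-2.62) were lowest. Against VAT, 3242 genes differed (2121 higher, 1121 lower). Macrophage genes were lower in PVAT for 24 of 27 (median -1.58, adjusted p = 3.09e-15, but adjusted p = 0.205 with an estimated correlation), with the proton pump subunit Atp6v0d2 (-2.97) and Mmp12 (-2.63), and brown genes were higher for 20 of 23 (median 1.47, adjusted p = 4.73e-14, but adjusted p = 0.16 with an estimated correlation), led by Cidea (3.46) and Ucp1 (3.45).

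HFD PVAT 2 and HFD VAT 2 stood apart from their groups and resembled each other. Their correlation was 0.983, against 0.963 to 0.965 with the other arrays of their own depots, and the mean of the brown list was 10.06 in HFD VAT 2 against 8.05 and 8.41 in the other HFD VAT arrays. Macrophage genes had a mean of 10.86 in HFD PVAT 2 against 9.13 and 9.10, and cardiac genes a mean of 9.12 in HFD VAT 2 against 7.69 and 7.75. Without these arrays the HFD difference between PVAT and VAT was 5.17 for Ucp1 and 4.92 for Cidea, the median of macrophage genes was -2.33, and 4124 genes differed. With an estimated correlation the brown list then passed against SAT (adjusted p = 0.00577) and VAT (0.00341), as did oxidative phosphorylation (0.0108 and 0.00907), fatty acid oxidation (0.0108 and 0.00907), tricarboxylic acid cycle (0.00715 and 0.00497) and extracellular matrix (0.0465 and 0.0344). The white list passed against SAT (0.0356). The median of macrophage genes against SAT went from -0.06 to -0.73 (adjusted p = 8.43e-06, but adjusted p = 0.388 with an estimated correlation). The count of 3242 was 1560 without HFD PVAT 3, 1807 without HFD VAT 1, 1890 without HFD PVAT 1 and 0 when these 6 arrays were fitted alone, and that of PVAT and BAT was 197 without HFD BAT 3.

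The diet comparisons asked what high fat feeding changed in each depot. In PVAT, no gene passed the limma test (0 genes, with 1393 at an unadjusted p under 0.05), and every gene value here is one that did not pass. Ucp1 had near means (13.52 ± 0.20 under HFD and 13.62 ± 0.08 under ND, -0.09, SE 0.80, adjusted p = 0.986), and Cidea (-0.21), Ppargc1a (-0.75), Elovl3 (-1.13) and Dio2 (-1.41, adjusted p = 0.159) had negative values. The smallest p-values belonged to Mc5r, a melanocortin receptor (-0.92, adjusted p = 0.0505), the glycogen regulator Ppp1r3b (-0.81, 0.123), Acsl5 (-0.91), Dhrs7 (-0.84) and Gsta3 (-1.04) on the lower side and Sncg (1.11, 0.159), Mmp12 (2.44), Gpnmb (2.66), Zc3h3 (0.66) and Mest (2.33) on the higher side. Lep was at 0.88, Retn at -0.89, and the macrophage genes Adgre1 at 1.08 (adjusted p = 0.528), Cd68 at 1.20 and Itgax at 1.43. Many of these values moved when HFD PVAT 2 and HFD VAT 2 were left out, and none passed: Mmp12 1.34, Gpnmb 1.73, Lep 0.24, Adgre1 0.36, Cd68 0.51, Itgax 0.55, Ppargc1a -0.47, Cidea -0.05 and Ucp1 0.02. Other settings called 5 genes without HFD PVAT 3, 2 without ND PVAT 1, 6 with array weights and 1 with trend and robust moderation. Leaving out HFD PVAT 2 and HFD VAT 2 gave 0.

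As a set, genes of fatty acid and triglyceride synthesis were lower under HFD (median -0.47, adjusted p = 3.81e-11, but adjusted p = 0.124 with an estimated correlation), with 7 of 21 lower when adjusted over the list alone and 0 over all genes. Cholesterol synthesis was lower (median -0.31, 2 of 16 over the list alone, adjusted p = 1.73e-06, but adjusted p = 0.368 with an estimated correlation), and so was mesothelium (median -0.26, 5 of 13, adjusted p = 6.7e-08, but adjusted p = 0.124 with an estimated correlation). The macrophage list was higher (median 0.62, 5 of 27, adjusted p = 1.12e-12, but adjusted p = 0.368 with an estimated correlation), as was the extracellular matrix list (median 0.40, 1 of 25, adjusted p = 1.45e-10, but adjusted p = 0.368 with an estimated correlation). Both moved with HFD PVAT 2, and without HFD PVAT 2 and HFD VAT 2 their medians were 0.14 and 0.15. In the same fit mesothelium passed with an estimated correlation (median -0.30, adjusted p = 0.0412). There fatty acid oxidation (median 0.22, adjusted p = 0.458 with an estimated correlation), tricarboxylic acid cycle (0.11, 0.608), T lymphocyte (0.24, 0.675), endothelium (0.19, 0.458) and nerve lists (0.09, 0.512) were higher with the preset one. With the preset correlation 8 further lists passed, none of them with a member past the test over all genes. They were B lymphocyte (median -0.59, adjusted p = 0.368 with an estimated correlation), skeletal muscle (-0.21, 0.702), cardiac muscle (-0.36, 0.702), circadian clock (-0.13, 0.702) and oxidative phosphorylation (-0.08, 0.761) on the lower side, and thymocyte (0.40, 0.496), cytokines (0.16, 0.412) and endothelium (0.07, 0.702) on the higher. Each of these 8 lost the call without at least 1 array. B lymphocyte lost it without ND PVAT 2 (-0.16, adjusted p = 0.0868). Leaving out HFD PVAT 2 ended the call of oxidative phosphorylation, whose median turned to 0.02 (adjusted p = 0.959), skeletal muscle (0.193), cardiac muscle (0.512), clock (0.309) and cytokines (0.309). HFD PVAT 1 did so for thymocyte (adjusted p = 0.81), endothelium (0.39) and skeletal muscle (0.0682). ND PVAT 1 (adjusted p from 0.0617 to 0.456) and ND PVAT 3 (0.0516 to 0.124) each ended those of oxidative phosphorylation, cardiac muscle, clock and thymocyte. ND PVAT 1 also ended cytokines and endothelium, and ND PVAT 3 skeletal muscle. Endothelium was also lost without HFD PVAT 3 (0.242) or ND PVAT 2 (0.114).

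In BAT, 13 genes passed, 4 higher and 9 lower under HFD. Hsd11b1, which regenerates active glucocorticoid, was 2.6-fold lower (-1.38, SE 0.22, adjusted p = 0.00902), and the G protein regulator Rgs2 (-1.34), the acyl-CoA synthetase Acsl5 (-1.21), Tmem79 (-0.94), Mc5r (-0.89), Cyp1a1 (-0.84), Ppp1r3b (-0.78) and Aacs (-0.71, adjusted p = 0.0498) fell as well. Sncg, gamma synuclein, was 2.33-fold higher (1.22, SE 0.23, adjusted p = 0.0368), with the muscle stress protein Ankrd23 (1.09), the prostaglandin dehydrogenase Hpgd (0.97) and Pcolce of collagen processing (0.85). Thermogenic genes gave no call: Ucp1 was at 0.03 (adjusted p = 1), Dio2 at -1.16 (0.218) and Cidea at -0.18, and Lep (1.29, 0.545) and Adgre1 (0.97) did not pass. No list had a member past the test over all genes. Fatty acid synthesis was lower (median -0.46, 8 of 21 over the list alone, adjusted p = 2.47e-13, but adjusted p = 0.0712 with an estimated correlation), and so was cholesterol synthesis (median -0.44, 8 of 16, adjusted p = 6.23e-12, but adjusted p = 0.0712 with an estimated correlation). Skeletal muscle genes were higher (median 0.80, 13 of 16 over the list alone, adjusted p = 4.38e-20, but adjusted p = 0.0712 with an estimated correlation), with list means of 11.10 to 11.57 under HFD and 9.88 to 10.97 under ND. Immediate early (median 0.48, adjusted p = 0.0712 with an estimated correlation), macrophage (0.79, 0.298), extracellular matrix (0.35, 0.298), endothelium (0.19, 0.298) and cytokine lists (0.18, 0.298) were higher with the preset correlation, the last not without HFD BAT 1 (adjusted p = 0.122). All 12 genes named as passing lost the call without HFD BAT 2, where 1 gene passed, and 4 passed without HFD BAT 1, 5 without ND BAT 2, 8 without ND BAT 3 and 363 with array weights. Without HFD PVAT 2 and HFD VAT 2, arrays of other depots, the count was 38.

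In SAT, 277 genes passed, 69 higher and 208 lower under HFD. Lipf, a lipase, was 12.7-fold higher (3.67, SE 0.47, adjusted p = 0.00217), and Cyp2f2, a cytochrome P450, was 8.56-fold lower (-3.10, SE 0.42, adjusted p = 0.00268). The imprinted genes Mest (2.63) and Peg3 (1.01), Adh6b (1.29), the matrix signal protein Ccn1 (1.21), the retinol binding protein Rbp7 (1.05), the tight junction protein Cldn5 (1.05) and Ptchd4 (1.04) rose. Acaca, acetyl-CoA carboxylase (-1.61), Fads1, a fatty acid desaturase (-1.30), and Acly, ATP citrate lyase (-1.27), fell, with the antioxidant Gpx3 (-1.48), Tmem53 (-1.24), Tst (-1.14) and the antibody segment Igkv8-30 (-1.89). The fatty acid and triglyceride synthesis list had 2 of 21 lower (10 lower and 1 higher over the list alone, median -0.29) and did not pass (adjusted p = 0.0827). It did without HFD PVAT 2 and HFD VAT 2 (adjusted p = 0.0148, but adjusted p = 0.765 with an estimated correlation). T lymphocyte genes fell for 3 of 16 (11 over the list alone, median -0.62, adjusted p = 0.000284, but adjusted p = 0.881 with an estimated correlation), namely Ccr7 (-0.94), Cd3e (-0.86) and Lef1 (-0.69), and B lymphocyte genes for 1 of 17, Ighm (-1.10, list median -0.70, adjusted p = 0.00183, but adjusted p = 0.881 with an estimated correlation). The means of the B lymphocyte list, with its lymph node markers, were 9.63, 9.21 and 10.23 under HFD and 10.15, 10.40 and 10.81 under ND. Extracellular matrix had 0 of 25 past the test (median 0.12, adjusted p = 0.0102, but adjusted p = 0.881 with an estimated correlation) and lost the call without HFD SAT 3 (0.267) or ND SAT 1 (0.0607). Ucp1 (-1.46, adjusted p = 0.216) and Lep (1.09, 0.142) did not pass.

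The SAT count rested on single arrays: 3 genes passed without HFD SAT 1, 5 without HFD SAT 2, the array with the smallest SD, 6674 without HFD SAT 3, 31 without ND SAT 1, 3 without ND SAT 2 and 19 without ND SAT 3. Lipf, Cyp2f2 and Gpx3 passed each time, and the other genes named here did not. By quantile normalization 164 genes passed, 84 higher and 80 lower, and 0 passed when the 6 SAT arrays were fitted alone, where limma had only these to estimate the spread (5010 genes had an unadjusted p under 0.05 in the fit of all arrays).

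In VAT, HFD changed 3241 genes, 842 higher and 2399 lower (205 and 197 by a log2 of at least 1). Atp6v0d2, a proton pump subunit of macrophages and osteoclasts (probe set 10511779), was 21.3-fold higher (12.53 ± 0.19 against 8.12 ± 0.44, 4.41, SE 0.71, adjusted p = 0.000268). Agt was 6.15-fold lower (-2.62, SE 0.26, adjusted p = 2.31e-06). Rgs1 (3.74), Tm4sf19 (3.65), the melatonin-related receptor Gpr50 (3.49) and Il7r (3.38) were also among the largest rises, and Adgrg2 (-2.72), Dennd2d (-2.38), Cyp2f2 (-2.23), Gsta3 (-2.18), Ppil6 (-2.15) and Mmrn1 (-2.09) among the largest falls. Of the tested genes, 39% had no overlap between diets, where chance gives 10%.

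Of 27 macrophage genes 16 rose and 1 fell (19 and 1 over the list alone, median 1.29, adjusted p = 6.45e-12, but adjusted p = 0.368 with an estimated correlation), with the elastase Mmp12 (3.57), Gpnmb (3.37), the integrin Itgax (3.07) and Cd68 (1.90) higher. Adgre1 was higher by 1.67, but not without HFD VAT 1 (1.55, adjusted p = 0.0558). Cytokine genes rose for 4 of 23 and fell for 1 (median 0.21, adjusted p = 0.0065, but adjusted p = 0.394 with an estimated correlation), with the interleukin receptor antagonist Il1rn (2.42) and the chemokine Ccl3 (1.60). Extracellular matrix genes rose for 4 of 25 and fell for 1 (median 0.28, adjusted p = 0.000805, but adjusted p = 0.524 with an estimated correlation), with Timp1 (1.64) and Postn (1.25).

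Mesothelium genes fell for 13 of 13 (median -0.75, adjusted p = 6.73e-11, but adjusted p = 0.0573 with an estimated correlation), with Upk1b (-1.72) and Gpm6a (-1.32). Leaving out HFD PVAT 2 and HFD VAT 2 gave this list 0.0453 with an estimated correlation. Endothelium fell for 13 of 16 (median -0.50, adjusted p = 3.95e-06, but adjusted p = 0.368 with an estimated correlation), with the phosphatase Ptprb (-0.82) and Emcn (-0.67), and smooth muscle for 8 of 15 (median -0.66, adjusted p = 0.000685, but adjusted p = 0.394 with an estimated correlation), with Tagln (-1.18) and Myh11 (-1.16). White adipocyte genes fell for 10 of 19 (median -0.57, adjusted p = 0.000685, but adjusted p = 0.368 with an estimated correlation), with Hoxc8 (-1.59) and Retn (-1.20), and pan-adipocyte genes for 10 of 17 (median -0.44, adjusted p = 0.000685, but adjusted p = 0.368 with an estimated correlation), with the glucose transporter Slc2a4 (-0.88) and Adipoq (-0.51). Vasoactive genes fell for 8 of 15 (median -0.51, adjusted p = 0.000285, but adjusted p = 0.171 with an estimated correlation), with the endothelin receptor Ednrb (-0.79) beside Agt. Positional genes fell for 12 of 33 (median -0.29, adjusted p = 0.000217, but adjusted p = 0.368 with an estimated correlation), with Hoxc5 (-1.17) and Hoxc6 (-1.07). Clock genes fell for 4 of 18 (median -0.42, adjusted p = 0.0065, but adjusted p = 0.495 with an estimated correlation), with Per3 (-1.11) and Tef (-0.61), and fatty acid synthesis for 6 of 21 (median -0.37, adjusted p = 0.00362, but adjusted p = 0.495 with an estimated correlation), with Pnpla3 (-0.68).

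Lists that HFD VAT 2 moved also passed: brown adipocyte (1 of 23 higher and 1 lower, median 0.34, adjusted p = 0.000872, but adjusted p = 0.524 with an estimated correlation), fatty acid oxidation (1 of 19 higher, median 0.20, 0.629 with an estimated correlation), cardiac muscle (1 of 13 higher, median 0.50, 0.524) and T lymphocyte (1 of 16, median 0.19, 0.553). Without HFD VAT 2 their medians were -0.02, -0.24, 0.05 and 0.07, and none passed (adjusted p from 0.0722 to 0.954). Fatty acid oxidation also lost the call without ND VAT 1 (adjusted p = 0.0519) or ND VAT 2 (0.0626). Ucp1 had a mean of 10.08 ± 2.99 under HFD and 8.66 ± 0.78 under ND (1.42, adjusted p = 0.211) and a difference of -0.19 without the 2 arrays that stood apart. Without both, oxidative phosphorylation (13 of 54 lower, median -0.25, adjusted p = 1.16e-05, but adjusted p = 0.38 with an estimated correlation) and the tricarboxylic acid cycle (12 of 16 lower, median -0.39, adjusted p = 8.05e-06, but adjusted p = 0.237 with an estimated correlation) were lower, as was Ppargc1a (-1.06, adjusted p = 0.00245). Lep (0.18), Tnf (0.37) and Saa3 (-0.15) did not pass. The count of 3241 was 1708 without HFD VAT 1, 1795 without ND VAT 3 and 5003 with array weights.

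**Figure D3:**
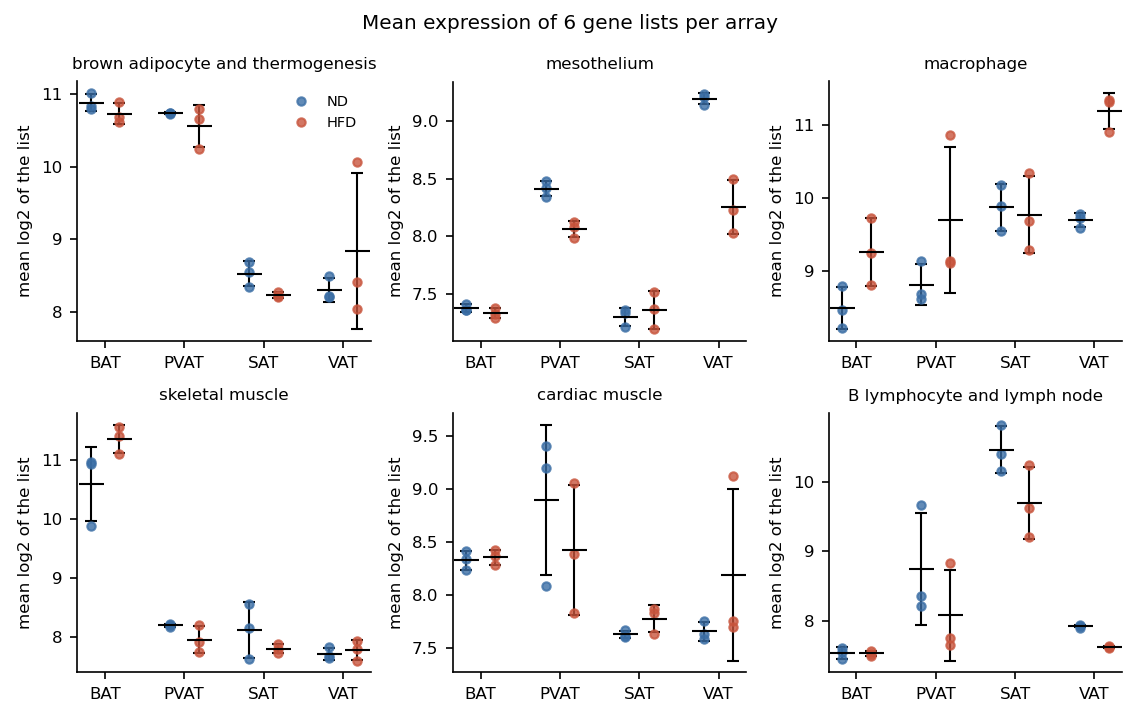
Mean log2 level of 6 gene lists in each of the 24 arrays by depot and diet, one point per array, with the group mean and SD. HFD PVAT 2 lies at 10.86 for macrophage genes and HFD VAT 2 at 10.06 for brown genes, both outside the other arrays of their groups.

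Interaction tests asked whether the diet response of PVAT differed from that of each other depot. Against VAT, 232 genes passed, 207 with a higher and 25 with a lower diet response in PVAT. The response of Agt was higher in PVAT by 2.40 (SE 0.37, adjusted p = 0.00386), with a diet difference of -0.22 in PVAT and -2.62 in VAT. Ppil6 (2.12), Adgrg2 (1.91), Hoxc8 (2.29) and Nnat (2.19) followed, and the dehydrogenase Dhrs9 (-2.75), Sycp3 of meiotic chromosomes (-2.0), Rgs2 (-1.85), Otop1 (-1.85) and Dio2 (-1.72) had the lower response. Dio2 (adjusted p = 0.127), Otop1 (0.0703) and Hoxc8 (0.0727) did not pass without HFD PVAT 2 and HFD VAT 2. Agt, Ppil6, Adgrg2, Dhrs9 and Rgs2 passed whichever 1 array was left out, Otop1 passed without HFD VAT 3 alone, and Dio2 without HFD PVAT 3 or HFD VAT 3 alone.

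Against BAT (0 genes by limma, 519 at an unadjusted p under 0.05, and 0 with array weights) and SAT (0 genes by limma, 1533 unadjusted, and 882 with array weights), no gene passed. Without HFD SAT 3, 1249 genes passed against SAT, and 1 without ND SAT 1. Against BAT, 1 passed without ND PVAT 1, without HFD BAT 2 or without ND BAT 1. A different diet response of PVAT and these depots was thus not shown for any gene. The count of 232 against VAT was 86 without HFD VAT 1, 104 without ND PVAT 2, 109 without HFD VAT 2, 112 without HFD PVAT 3, 122 without ND VAT 3, 124 without HFD PVAT 1, 149 without ND PVAT 1, 417 without HFD PVAT 2 and 556 without HFD VAT 3. It was 455 without both arrays that stood apart and 424 with replicate number as a block.

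**Figure D4:**
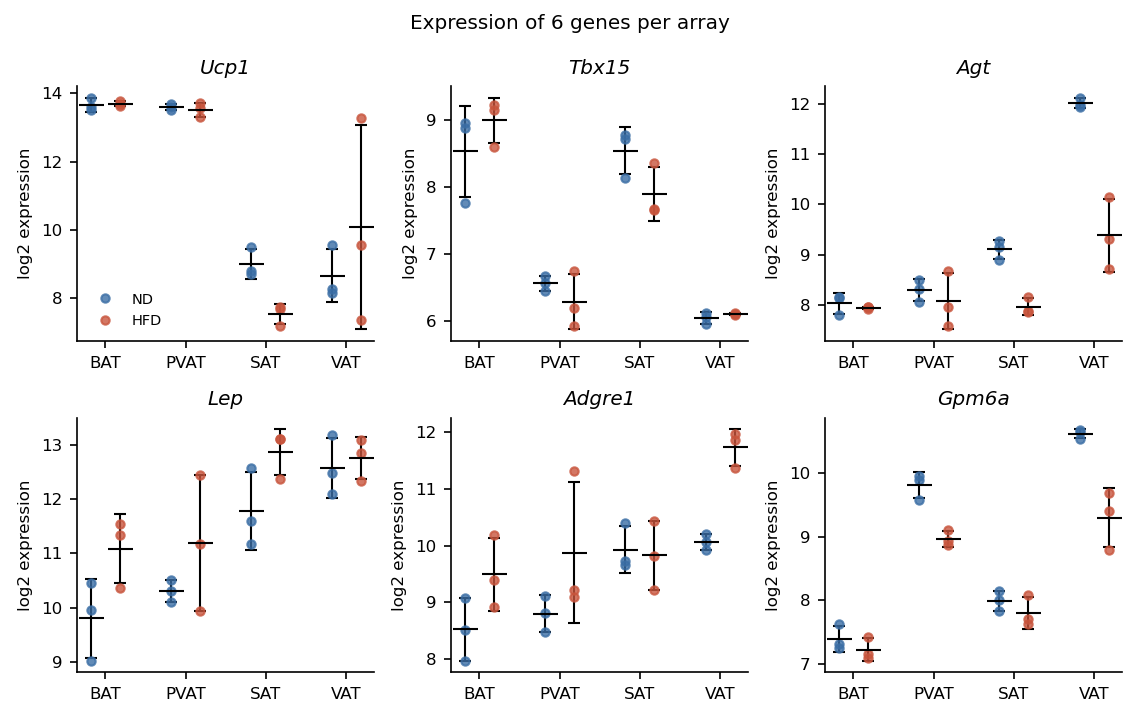
Log2 level of Ucp1, Tbx15, Agt, Lep, Adgre1 and Gpm6a in each array by depot and diet, one point per array, with the group mean and SD. Ucp1 is at 13.62 ± 0.08 in ND PVAT and 13.66 ± 0.20 in ND BAT, and Agt fell by 2.62 with HFD in VAT.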

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

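Among the tests in this part, the counts of other splits, the fits without both HFD PVAT 2 and HFD VAT 2, the stricter exclusion of immune genes and the tests of heart muscle and white adipocyte genes were chosen only after the result was seen.

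These are interaction tests of PVAT against another depot. Against VAT, 232 genes passed. The response was higher in PVAT for Agt (2.40), Hoxc8 (2.29), Nnat (2.19), Ppil6 (2.12) and Adgrg2 (1.91), and lower for Dhrs9 (-2.75), Sycp3 (-2.0), Rgs2 (-1.85), Otop1 (-1.85) and Dio2 (-1.72). Of 100 splits of the same arrays 8 gave as many genes, the highest other 2296. Splits that keep the VAT diets whole still hold the VAT diet effect, so they cannot decide, and chance is not excluded.

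The lists with a higher diet response in PVAT than in VAT were white adipocyte (median 0.70, adjusted p = 0.135 with an estimated correlation), endothelium (0.63, 0.135), smooth muscle (0.56, 0.396), mesothelium (0.50, 0.129), vasoactive (0.48, 0.129), pan-adipocyte (0.27, 0.31) and positional genes (0.25, 0.271). Those with a lower response were cardiac muscle (-0.81, 0.271), macrophage (-0.67, 0.641), brown adipocyte (-0.48, 0.395), cholesterol synthesis (-0.44, 0.216), B lymphocyte (-0.44, 0.641), skeletal muscle (-0.25, 0.641) and oxidative phosphorylation (-0.15, 0.641). Without HFD VAT 2 the brown list did not pass (-0.10, adjusted p = 0.192) and the oxidative phosphorylation list turned to 0.12 (0.00765). Without HFD PVAT 2, oxidative phosphorylation (-0.03, 0.147), skeletal muscle (-0.18, 0.0646) and B lymphocyte (-0.28, 0.202) did not pass, the last also not without HFD PVAT 1 (0.0999) or ND PVAT 2 (0.957). With both arrays left out the brown (0.03), cardiac (-0.22), B lymphocyte (-0.24) and skeletal muscle lists (-0.12) did not pass, oxidative phosphorylation was at 0.23 (adjusted p = 4.54e-06, 0.345 with an estimated correlation), and fatty acid oxidation (0.50, 2.58e-05, 0.302 with an estimated correlation) and the tricarboxylic acid cycle (0.48, 1.43e-09, 0.156) passed with a higher response in PVAT. The macrophage median went to -1.46 (0.156 with an estimated correlation), and Itgax (-2.71, adjusted p = 0.000118) and Ccl2 (-1.25, 0.0325) passed with a lower response.

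Against BAT no gene passed, and the lists that passed with the preset correlation were skeletal muscle (median -1.03, adjusted p = 0.141 with an estimated correlation), cardiac muscle (-0.62, 0.809), B lymphocyte (-0.58, 0.555), immediate early (-0.53, 0.212), smooth muscle (-0.22, 0.912), mesothelium (-0.17, 0.212), endothelium (-0.12, 0.924) and circadian clock (-0.09, 0.912), with a lower response in PVAT, and thymocyte (0.38, 0.555) with a higher one. Skeletal muscle, mesothelium and immediate early genes passed whichever 1 array was left out. Skeletal muscle genes rose by 0.80 in BAT, where the amount dissected may be the source. The other 6 lists lost their call when 1 array was left out, given here with the adjusted p: thymocyte (HFD PVAT 1 0.625, ND PVAT 1 0.269), B lymphocyte (ND PVAT 2 0.101), cardiac muscle (HFD PVAT 2 0.165, ND PVAT 1 0.269), endothelium (HFD BAT 2 0.232, HFD BAT 3 0.0556, HFD PVAT 2 0.697, ND BAT 2 0.112, ND PVAT 1 0.137, ND PVAT 3 0.262), smooth muscle (HFD BAT 2 0.202, HFD PVAT 1 0.123, HFD PVAT 2 0.256, ND BAT 2 0.0748, ND BAT 3 0.115, ND PVAT 1 0.989) and clock (HFD BAT 3 0.293, HFD PVAT 2 0.328, ND BAT 2 0.342, ND BAT 3 0.073, ND PVAT 1 0.154, ND PVAT 3 0.18). With a real count of 0 genes all 100 splits reach it and decide nothing. The highest other, 148, points to a structure of the samples.

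Against SAT no gene passed, and the lists that passed with the preset correlation were macrophage (median 0.87, adjusted p = 0.743 with an estimated correlation) and T lymphocyte (0.75, 0.584), with a higher response in PVAT, and cardiac muscle (-0.49, 0.584), mesothelium (-0.47, 0.178), cholesterol synthesis (-0.39, 0.414), epididymis epithelium (-0.27, 0.584) and pan-adipocyte (-0.14, 0.584), with a lower one. Without HFD PVAT 2 the macrophage list did not pass (0.40, adjusted p = 0.0849) and the epididymis list (HFD PVAT 2 0.0558, HFD PVAT 3 0.0507, HFD SAT 2 0.263, ND PVAT 1 0.223, ND SAT 1 0.0979, ND SAT 3 0.0707) and pan-adipocyte list (HFD SAT 3 0.0717, ND PVAT 3 0.114, ND SAT 3 0.0705) each lost their call without 1 of several arrays. Here too all 100 splits reach the real count of 0 and decide nothing. The highest other was 1499, which for the same reason does not tell a structure of the samples from a diet effect.

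The interaction with VAT involves HFD PVAT 2 and HFD VAT 2, each of which lay toward the other depot. Over 820 genes that tell the depots apart under ND, the share of the other depot was estimated. It was 41.4% in HFD PVAT 2 (95% interval 39.8 to 42.5) and 44.6% in HFD VAT 2 (42.9 to 46.9). All intervals given are over genes and hold no spread between pools. Both shares lie in the 35 to 65% set for exchanged PVAT and VAT tubes of 1 of the 2 pooled mice. Such an exchange may be the source. RNA of both depots by another route may also be. The smallest of 4 median shifts toward the other depot was 0.129 log2 (95% interval -0.03 to 0.333), under the 0.2 set against a mixture. A mixture of these shares would move those positional genes by only 0.16, so the bound was too high and this stays open. Browning of 1 VAT pool is argued against as the whole source. In HFD VAT 2, 9 heart muscle genes lay a median of 1.98 above HFD BAT (0.508 to 2.14). Their rise of 1.85 over the other HFD VAT arrays exceeds the 0.82 of the estimated mixture, which misses it too. Cardiac list means were 9.12 in HFD VAT 2, 7.83 to 9.05 in HFD PVAT and 8.08 to 9.40 in ND PVAT. Positional genes, shifted by 0.332 (0.166 to 0.519), leave browning open for the rest. Inflammation of 1 PVAT pool is likewise argued against as the whole source. In HFD PVAT 2, 15 white adipocyte genes lay a median 0.909 above the other HFD PVAT arrays (0.264 to 1.16, a mixture gives 1.0). Pan-adipocyte genes stayed at -0.09 (-0.19 to 0.06). The shift of 0.316 (0.253 to 0.415) of VAT genes not classed as immune fell to 0.0757 (0.0145 to 0.249) with a stricter immune bound. This leaves inflammation open for the rest, and a change of the fat cells themselves was not tested.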

How the results depend on the processing

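Chosen only after the result was seen were the fits that left out HFD PVAT 2 and HFD VAT 2 or HFD SAT 2, the score axes without HFD VAT 2 or without muscle or immune genes, the brown list minus the white list and the gene by gene form of the array weights. Where no cause is named below, the cause was not tested. With a log2 difference of at least 1 as a further condition, which by construction leaves fewer genes, the counts were 150 (PVAT against BAT), 1165 (PVAT against SAT), 812 (PVAT against VAT), 1695 (BAT against SAT), 1358 (BAT against VAT) and 492 (SAT against VAT) under ND, 146, 845 and 609 for PVAT against BAT, SAT and VAT under HFD, 5, 26 and 402 for diet in BAT, SAT and VAT, and 94 for the interaction of PVAT and VAT. Array weights gave 1125 (PVAT against BAT) and 4576 (SAT against VAT) under ND, 660 and 7236 for PVAT against BAT and SAT under HFD, 6, 363, 8812 and 5003 for diet in PVAT, BAT, SAT and VAT, 882 and 648 for the interactions with SAT and VAT, and turned Tnf in SAT to 0.22. HFD SAT 1 had the highest weight, 7.53. The diet count in SAT was 24 with no filter, 524 with the filter at the 50th percentile, 94 with arrays centred on the median and 164 after quantile normalization. Diet in PVAT gave 1 gene with the filter at the 50th percentile and 1 with trend and robust moderation. With replicate number as a fixed block, a pairing that the check did not show for diet in SAT and that was not checked for interactions, diet in SAT gave 1359 and the interaction with VAT 424, and with a random block (correlation 0.0914) 615 and 397. With only the groups compared, and so fewer arrays for the spread, PVAT against SAT and VAT under HFD gave 1761 and 0, diet in BAT and SAT 32 and 0, and the interaction with VAT 43. Without HFD PVAT 2 and HFD VAT 2, diet in BAT gave 38 and the interaction with VAT 455, Itgax in PVAT against SAT under HFD turned to -0.63, and these list medians turned, with either form of camera: oxidative phosphorylation 0.0325 and macrophage -0.0877 in PVAT against BAT under HFD, oxidative phosphorylation 0.0234 for diet in PVAT, brown -0.0170 and fatty acid oxidation -0.24 for diet in VAT, and brown 0.0345 and oxidative phosphorylation 0.23 in the interaction with VAT. Of these turned lists the last alone passed (adjusted p = 4.54e-06, 0.345 with an estimated correlation). With an estimated correlation 45 of the 189 list calls then passed, 137 did not and 7 turned. Without HFD SAT 2, diet gave 2 genes in PVAT and 5 in SAT, and the interaction with VAT 375. Score differences were 1.69 to SAT and 1.54 to VAT with HFD arrays scored on an ND axis, and -1.76 to BAT and 2.18 to VAT with axis genes that differ by at least 2. Without muscle genes in the axis they were -0.50 to BAT and 2.29 to SAT, without muscle and immune genes -0.51 to BAT and 2.39 to VAT, with both conditions 3.05 to SAT and 4.11 to VAT, and for the brown list minus the white list -0.32 to BAT, 3.16 to SAT and 3.98 to VAT. Correlations of PVAT with BAT, SAT and VAT were 0.979, 0.949 and 0.958 with no filter, and 0.937 with VAT by Spearman. Leaving out each array in turn gave 191 to 484 genes for PVAT against BAT, 3644 to 4570 against SAT and 3111 to 3437 against VAT, 5420 to 6072 for BAT against SAT, 4454 to 5134 for BAT against VAT and 1131 to 2506 for SAT against VAT under ND. Under HFD it gave 197 to 309, 2830 to 5965 and 1560 to 3956 for PVAT against BAT, SAT and VAT. For diet it gave 0 to 5 in PVAT, 1 to 9 in BAT, 3 to 6674 in SAT and 1708 to 3953 in VAT, and for the interactions 0 to 1 with BAT, 0 to 1249 with SAT and 86 to 556 with VAT. Scores stayed at -0.86 to -0.65 to BAT, 1.94 to 2.15 to SAT and 1.78 to 1.98 to VAT. The list medians that turned when 1 array was left out ranged from -0.24 to 0.42 (fatty acid oxidation, diet in VAT), -0.0877 to 0.72 (macrophage, PVAT against BAT under HFD), -0.32 to 0.12 (oxidative phosphorylation, interaction with VAT), -0.17 to 0.0234 (oxidative phosphorylation, diet in PVAT) and -0.36 to 0.00546 (smooth muscle, interaction with BAT). Of the named gene results, 520 kept their side of the threshold with arrays centred on the median, 521 after quantile normalization, 510 with no filter and 509 without HFD PVAT 2 and HFD VAT 2. Over all single arrays left out 3172 did and 338 lost their call. Among those kept, results past the test also kept their direction, while results that did not pass may have turned. Signal over background limits dim genes, which the filter removes, and the pooled pairs of mice hide differences between single animals.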

Other observations

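Among the tests in this part, those of the HFD SAT arrays (value range and lymph node), the fit without HFD PVAT 2 and HFD VAT 2, and the counts of other splits were chosen only after the result was seen, while the test of skeletal muscle in BAT was chosen before.

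Single positional genes, which set the place of tissues in the embryo, differed between the 4 depots under ND (genes chosen after their values were seen), while the fixed list of 33 mostly went both ways. It had 0 genes higher and 4 lower in PVAT against BAT, 6 and 11 in PVAT against SAT, 4 and 10 in PVAT against VAT, 7 and 6 in BAT against SAT, 6 and 7 in BAT against VAT and 6 and 4 in SAT against VAT. As a set it passed in the first of these alone (adjusted p = 0.00341, but 0.617 with an estimated correlation), with adjusted p from 0.0857 to 0.886 in the others. Tbx15 was higher in SAT and in BAT than in VAT, by 2.49 and 2.49, while PVAT lay below SAT (-1.98) and BAT (-1.97) and did not differ from VAT past the test (0.51). Tbx5 was highest in PVAT and BAT, 1.86 and 1.77 above VAT, with SAT between (0.87). Hoxc10 was higher in SAT than in VAT (1.49), and lower in PVAT (-1.5) and BAT (-1.46) than in SAT. Hoxa5 was lower in SAT than in VAT (-0.58), with PVAT 1.29 and BAT 1.16 above SAT, and Zic1 was higher in BAT than in SAT (1.15) and VAT (1.14).

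Vasoactive genes were lower in BAT than in VAT for 11 of 15 members (median -0.74, adjusted p = 5.24e-06, but adjusted p = 0.0628 with an estimated correlation) and in SAT for 3 of 15 (median -0.36, adjusted p = 0.000122, but 0.0604 with an estimated correlation), with Agt (-2.90) and Ptgis (-1.41) lower in SAT. Both list calls passed with an estimated correlation without HFD PVAT 2 and HFD VAT 2, a fit chosen after the result was seen (adjusted p = 0.0112 and 0.0277).

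Skeletal muscle genes were higher in BAT than in PVAT. Over the 6 BAT arrays the deviations of the 16 genes from their group means had a mean pairwise correlation of 0.936, against 0.244 at the upper end of the central 95% of 1000 random lists of like level, and 100% of the genes were higher in ND BAT than in ND PVAT by 1 log2 or more. Muscle tissue in the dissections would give this, and may be the source. A muscle-like state of the brown fat cells themselves was not tested and stays open.

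The diet count in SAT changed with each array. A narrow value range of HFD SAT 2, which had the smallest SD, is argued against as the whole source: after quantile normalization, which gives all arrays the same range, the counts without HFD SAT 1, 2 and 3 were 7, 8 and 4913, the highest 702 times the lowest (3, 5 and 6674 before). The slope of an array's deviations from the other 2 on the ND level went from -0.179 to -0.0846 log2 per log2 in HFD SAT 2 and from 0.172 to 0.0752 in HFD SAT 3, slopes that by construction mirror each other, so they do not tell which array departs. The T and B lymphocyte genes differed between HFD SAT 3 and HFD SAT 2 by a median of 0.572 more than other genes of a like level (33 genes, interval 0.161 to 0.753), so the pools differed in these genes, but by less than the 1 set for different amounts of lymph node and with an interval that reaches past the 0.3 set against it, which leaves that source open. No other biological difference between the pools was tested.

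For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were, under ND, 374 and 3 (PVAT against BAT), 4893 and 2 (PVAT against SAT), 3968 and 0 (PVAT against VAT), 6757 and 0 (BAT against SAT), 5602 and 1 (BAT against VAT) and 2311 and 0 (SAT against VAT). Under HFD they were 311 and 0 (PVAT against BAT), 4197 and 377 (PVAT against SAT) and 3242 and 1970 (PVAT against VAT, a split that sets HFD PVAT 1, HFD PVAT 3 and HFD VAT 2 against the rest). For diet they were 13 and 0 in BAT and 3241 and 2 in VAT. In each of these the real split alone, 1 of 10, gave as many genes. In PVAT all 10 splits gave 0 genes. In SAT 2 of 10 gave as many, the real 277 and 1725 for HFD SAT 1, HFD SAT 2 and ND SAT 1 against the rest, which points to a structure of the samples other than diet.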
